A study of Mus musculus with 6 samples.

How the data were processed

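RNA from polysome fractions of the mouse macrophage-like line RAW264.7 was sequenced in 6 libraries, all labelled M2. Of these, 3 came from cells given BMH-21, an inhibitor of RNA polymerase I, and 3 from cells given the DMSO vehicle. Groups and replicate numbers were taken from the sample titles. Polysome fractions hold mRNA bound by several ribosomes, so a value reflects both how much of an mRNA a cell held and how much of it was on polysomes. No unfractionated RNA was used here, so these parts were not separated. Mitochondrially encoded and nuclear-retained RNAs were also measured, and whether they were on polysomes was not tested. Per the labels, BMH-21 was used at 500 nM for 24 h, beginning 24 h after polarization. The treatment text in the labels also speaks of bone-marrow-derived macrophages and of IL-4 at 20 ng/ml or interferon gamma with LPS. The cell line and the M2 state are therefore as titled, and the polarizing agent is not stated for the line itself. The label of DMSO replicate 2 names polyadenylated RNA where the other 5 name total RNA. Per the labels, all libraries were made with the same oligo-dT enrichment kit, which is not stated there to mark the strand.

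The deposited table holds normalised values for 19233 genes in 6 columns, whose unit was read as FPKM (fragments scaled by transcript length and library size) from the values and is not named per the labels. Per the submitters' processing notes, Trimmomatic 0.38, HISAT2 and SAMtools were used with the mm10 build. The counting and normalising tools and the gene annotation are not given in the sources used here. FPKM values are shares of a library, so a rise of a few abundant genes lowers all others, and a change in total RNA per cell is not measured. Values of overlapping genes, antisense partners and near-identical copies (ribosomal protein genes and their pseudogenes, Lyz1 and Lyz2, the H2-Q genes, Hmga1 and Hmga1b, histone genes, and Atp6v0c with its pseudogene) are uncertain, because the way reads were split between them is not given.

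Depth was estimated from the steps between low values. Of 1969 to 2326 low, single-transcript genes per library, 64.4% to 68.2% came out within 0.01 of a whole number of reads, at most 20, which implied 21620000 to 24080000 reads in the DMSO libraries and 18780000 to 22570000 in the BMH-21 libraries. These shares were too low to recover read counts, so no count model was fitted.

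Values were transformed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 samples were tested, which kept 9748 genes (50.7%). This filter was chosen after the table had been seen. Each gene was tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are on the log2(FPKM + 1) scale, BMH-21 minus DMSO, which understates the change of low genes. A planned count model was replaced by this planned fallback because the table held no counts. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. With 3 against 3 samples, an exact permutation test of a single gene cannot give a p below 0.10.

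The gene lists (38), the test, most alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera in limma, with a preset correlation of 0.01 and again with an estimated correlation, and tested by fry for a shared direction. Named genes were the 8 largest rises and the 8 largest falls among called genes with a mean log2(FPKM + 1) of at least 3, non-overlapping groups and a proper symbol, up to 4 members of each list in ascending order of p, and Polr1a, Polr1b, Arg1, Mrc1, Cdkn1a and Mdm2 whatever their values. The level limit stood in for a limit on log2 CPM written for counts. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule covers are not reported here. Gene positions, coding length, untranslated region length and GC content came from GENCODE M21 on GRCm38, the same assembly as mm10, and 97.3% of genes had a match. Because values are per gene, they cover its exons and cannot be assigned to an exon or untranslated region.

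Before use, the tests were tested on simulated data in which 50 of the 9748 genes were changed at each size. At 1.2-fold, 38% of the changed genes were recovered, at 1.5-fold 86%, at 2-fold 94% and at 4-fold 100%. Of 9548 unchanged genes 6 were called, and of 33 unshifted lists 0 were called. Most simulated genes were unchanged, and rises balanced falls. In the data 78.3% of genes were called and the all-gene median was not 0. The 6 calls therefore do not give the number of false calls in the data. Genes were simulated as independent of each other, so the list result does not show how camera behaves when members are correlated. Alternatives covered scaling, filter, pseudocount, a replicate block, the mitochondrial genes, the list test and leaving out each library. Quantile normalization, a robust variance model and an adjustment for coding length, untranslated region length and GC content were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.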

Results

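Gene levels were measured by RNA sequencing of polysome fractions, the part of a cell extract in which mRNAs carry several ribosomes, from RAW264.7 cells, a mouse line that resembles macrophages. Cells labelled M2, the alternatively activated state, had received BMH-21, a small molecule that inhibits RNA polymerase I, or its solvent DMSO, with 3 libraries in each group. RNA polymerase I is the enzyme that makes the ribosomal RNA precursor. The comparison asked how its inhibition changed the polysome-bound mRNAs of these cells. Low values implied 21620000 to 24080000 reads per DMSO library and 18780000 to 22570000 per BMH-21 library. At least 1 FPKM was reached by 9699 to 9770 genes in the DMSO libraries and by 9195 to 9261 in the BMH-21 libraries. Across genes, libraries of the same group correlated at 0.997 or more and libraries of different groups at 0.9627 to 0.964.

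With BMH-21, mRNAs of the cell division programme fell, among them all 49 tested mitosis genes, as did most genes of the ATF4 stress programme, which serve amino acid synthesis and uptake, and of nucleotide synthesis, glycolysis, cytosolic heat shock chaperones and ribosome assembly. Cytosolic ribosomal protein genes, p53 targets, immediate early genes, osteoclast-lineage genes, cholesterol synthesis genes and mitochondrially encoded mRNAs were higher as groups, relative to all genes. These list calls, higher and lower, were made with a preset correlation between members. None held with an estimated correlation (smallest adjusted p = 0.10 with an estimated correlation). For some lists, such as DNA replication and p53 targets, the estimate was no higher than the preset value. In those lists, correlation between members does not explain the loss. Among well-expressed genes the largest rises were those of Il1rn, the secreted antagonist of the interleukin-1 receptor, from 18.5 ± 0.56 to 289 ± 7.5 FPKM (SD, n = 3), and of the monocyte chemokine Ccl2, from 9.13 ± 0.55 to 85.4 ± 3.2 FPKM (SD, n = 3). Of the 2 M2 markers followed whatever their values, Arg1, the arginase of alternatively activated macrophages, fell from 4.29 ± 0.15 to 0.692 ± 0.044 FPKM, and the mannose receptor Mrc1 was at 1.2 ± 0.15 and 0.919 ± 0.13 FPKM.

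Of 9748 tested genes, limma called 7628 (78.3%) changed, 1938 higher and 5690 lower in BMH-21. A change of at least 2-fold was called for 147 higher and 511 lower genes, 658 in all, or 1199 with a pseudocount of 0.1. In 7782 tested genes (79.8%) the groups did not overlap, where chance gives 10%. The median change of all tested genes was −0.23 on the log2 scale, and the split into higher and lower rested on the scaling. Median-ratio scaling moved the all-gene median by 0.23 and gave 3643 higher and 3546 lower genes, upper-quartile scaling moved it by 0.20 and gave 3349 and 3883, and quantile normalization moved it by 0.24 and gave 3517 and 3498. List changes are therefore given relative to the median of all genes. Counts of list members that rose or fell are not relative, and stand beside 1938 higher and 5690 lower among all 9748 genes. More falls than rises in a list is thus not by itself a result about that list.

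**Figure D1:**
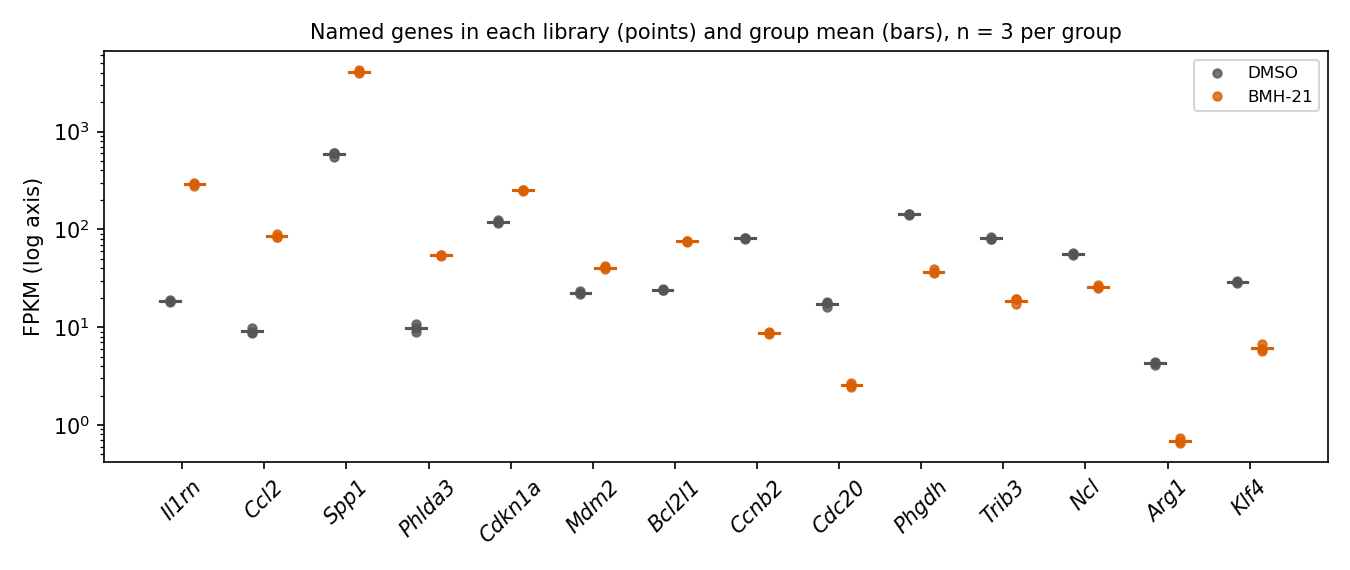
FPKM on a log axis for 14 genes named in the text, with each library as a point and the group mean as a bar (n = 3 per group). In each of them the 3 BMH-21 libraries lie apart from the 3 DMSO libraries, from Il1rn (18.5 against 289 FPKM) to Klf4 (28.9 against 6.15 FPKM), and their directions held under every scaling tried.

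Among the 8 largest rises of well-expressed genes, Il1rn (chromosome 2, 24336853 to 24351494) had a log2 fold change of 3.90 ± 0.04 (SE, limma adjusted p = 6.34e-12). Ccl2 (chromosome 11, 82035571 to 82037453) followed at 3.09 ± 0.05 (limma adjusted p = 1.43e-10). Spp1 (chromosome 5, 104435118 to 104441050), which encodes the secreted phosphoprotein osteopontin, rose from 585 ± 27 to 4099 FPKM, a log2 fold change of 2.81. Tm4sf19, a membrane protein gene, rose from 19.7 to 140 FPKM, and the chemokine gene Ccl9 from 188 to 1023 FPKM. Phlda3, a p53 target that restrains AKT, rose from 9.85 to 54.1 FPKM, and Plau, which encodes urokinase, from 7.51 to 34.0 FPKM. The histone gene H2ac18 rose from 64.2 to 322 FPKM, with the uncertainty of near-identical histone copies. With oligo-dT enrichment the H2ac18 value covers polyadenylated RNA, and a change in the polyadenylated share was not tested. In all 8, every BMH-21 library was above every DMSO library, as the rule for named genes required.

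Among the 8 largest falls of well-expressed genes, Cox6a2 (chromosome 7, 128205435 to 128206387), a subunit of cytochrome c oxidase best known from muscle, fell from 65.9 ± 1.8 to 5.03 ± 1.3 FPKM (SD, n = 3), a log2 fold change of −3.49 ± 0.13 (SE, limma adjusted p = 7.77e-09). Ccnb2 (chromosome 9, 70407692 to 70421547), a mitotic cyclin, fell from 80.8 ± 0.62 to 8.71 ± 0.13 FPKM, a log2 fold change of −3.07 ± 0.04 (limma adjusted p = 1.49e-11). Also in this group were Pttg1, which encodes securin, at −2.41, the S and G2 phase cyclin Ccna2 at −2.38, the anaphase activator Cdc20 at −2.35, the centrosomal kinase Nek2 at −2.30, the chromatin protein Hmgb2 at −2.26 and the mitotic kinase Aurkb at −2.22. In all 8, every BMH-21 library was below every DMSO library, which the same rule required.

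Genes of the cell cycle and of nucleotide supply fell together. All 49 tested genes of mitosis fell (median −1.15 relative to all genes, camera adjusted p = 1.1e-11, but adjusted p = 0.10 with an estimated correlation), with Ccnb1 going from 12.2 to 1.73 FPKM and the cytokinesis gene Racgap1 from 13.6 to 2.03 FPKM. Of 43 DNA replication genes, 41 fell and 2 rose (median −0.70 relative to all genes, camera adjusted p = 2.1e-06, but adjusted p = 0.10 with an estimated correlation). Examples were Rrm2, a subunit of ribonucleotide reductase, from 24.1 to 5.72 FPKM, thymidine kinase Tk1 from 17.6 to 4.04 FPKM and the helicase subunit Mcm5 from 9 to 2.19 FPKM. Of 26 nucleotide synthesis genes, 22 fell, 3 rose and 1 did not pass (median −0.57 relative to all genes, camera adjusted p = 0.0047, but adjusted p = 0.10 with an estimated correlation), with the purine enzyme Paics going from 59.3 to 24.8 FPKM and thymidylate synthase Tyms from 7.55 to 2.39 FPKM. Rrm1, Rrm2 and Tyms are in both the DNA replication and the nucleotide synthesis list. The counts of these 3 lists of mitosis, DNA replication and nucleotide synthesis were the same adjusted over the list alone.

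Of 37 genes of the integrated stress response driven by ATF4, 32 fell, 4 rose and 1 did not pass (median −0.87 relative to all genes, camera adjusted p = 2e-05, but adjusted p = 0.12 with an estimated correlation). Phgdh, which starts serine synthesis, fell from 143 ± 1.9 to 37.0 ± 1.7 FPKM, the mitochondrial serine enzyme Shmt2 from 71.2 to 16.2 FPKM, the pseudokinase Trib3 from 81.0 to 18.6 FPKM and Cth, which makes cysteine, from 18.3 to 4.22 FPKM. Of 24 cytosolic heat shock chaperones, 20 fell and 2 rose (median −0.35 relative to all genes, camera adjusted p = 0.0063, but adjusted p = 0.43 with an estimated correlation). Among them were the chaperonin subunit Cct2, from 127 to 51.8 FPKM, and the co-chaperone Stip1, from 26.4 to 10.8 FPKM. Of 27 glycolysis and glucose uptake genes, 20 fell and 1 rose (median −0.30 relative to all genes, camera adjusted p = 0.019, but adjusted p = 0.43 with an estimated correlation). Pgk1, phosphoglycerate kinase, fell from 297 to 118 FPKM and Gpi1, glucose phosphate isomerase, from 65.7 to 28.9 FPKM. After adjustment for coding length and GC content, the chaperone call was lost (camera adjusted p = 0.056) though its median, −0.39 relative to all genes, was no smaller, and the glycolysis call was lost (0.12) at a median of −0.23. With quantile normalization the glycolysis median was −0.56. Among 26 genes of endoplasmic reticulum chaperones and the unfolded protein response, 10 rose and 13 fell (camera adjusted p = 0.18, upward against a median of −0.10). Edem1, which acts in the degradation of misfolded glycoproteins, rose from 83.4 to 158 FPKM, and the oxidase gene Ero1l fell from 94.4 to 35.5 FPKM. Each of these 4 lists had the same counts adjusted over the list alone.

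The ribosome-related lists moved apart. Of 19 genes of the RNA polymerase I machinery, 4 rose and 11 fell, or 12 adjusted over the list alone, and the list was not called (camera adjusted p = 0.93). The initiation factor gene Ubtf fell from 20.2 to 11.4 FPKM, and Taf1b, part of the promoter selectivity factor, from 5.87 to 2.42 FPKM. Polr1a (chromosome 6, 71909053 to 71984935), the largest subunit, was at 0.982 ± 0.065 and 1.05 ± 0.031 FPKM, which did not pass (log2 fold change 0.05, limma adjusted p = 0.48). It did pass, as higher, with median-ratio scaling, at 0.19, with upper-quartile scaling, at 0.17, and with quantile normalization, at 0.34. Polr1b (chromosome 2, 129100995 to 129126594), the other large subunit, fell from 1.21 ± 0.059 to 0.821 ± 0.10 FPKM (log2 fold change −0.28, limma adjusted p = 0.0024), a call lost with median-ratio scaling, at −0.14, with quantile normalization, at −0.03, and after the length and GC adjustment, at −0.12. Of 64 ribosome biogenesis factors, 51 fell and 3 rose (median −0.23 relative to all genes, camera adjusted p = 0.0037, but adjusted p = 0.10 with an estimated correlation). The median was −0.14 after the length and GC adjustment (camera adjusted p = 0.018). Examples were nucleolin, Ncl, from 56.1 to 26.0 FPKM and the RNA helicase gene Ddx21 from 26.3 to 11.8 FPKM. Of 16 RNA polymerase III genes, 10 fell and 1 rose (camera adjusted p = 0.56), with Polr3c going from 37.2 to 20.8 FPKM. The counts of these last lists were the same adjusted over the list alone.

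Of 34 proteins of the small cytosolic ribosomal subunit, 27 rose, or 28 adjusted over the list alone, and 2 fell (median 0.65 relative to all genes, camera adjusted p = 8e-12, but adjusted p = 0.10 with an estimated correlation). Rps27l, a p53-responsive paralog, rose from 120 to 245 FPKM and Rps19 from 69.7 to 127 FPKM, while Rpsa, also known as the laminin receptor, fell from 291 to 186 FPKM. Of 49 large-subunit proteins, 34 rose, or 35 adjusted over the list alone, and 7 fell (median 0.47 relative to all genes, camera adjusted p = 5.2e-10, but adjusted p = 0.10 with an estimated correlation). Rpl39 rose from 61.6 to 130 FPKM, and the paralog Rpl22l1 fell from 19.6 to 5.08 FPKM. With quantile normalization the large-subunit call was lost (median 0.14, camera adjusted p = 0.27) and the small-subunit median shrank to 0.24 (camera adjusted p = 0.0086). The length and GC adjustment left the large-subunit median at 0.30 (camera adjusted p = 1.9e-05). Ribosomal protein genes have many near-identical pseudogenes, which leaves their single values uncertain. Of 40 translation initiation and elongation factors, 28 fell, or 29 adjusted over the list alone, and 7 rose, and the list was not called (median −0.10 relative to all genes, camera adjusted p = 0.18). Eif4b fell from 93.8 to 46.7 FPKM and Eif3d from 26.1 to 12.2 FPKM, while Tpt1, a translationally controlled protein, rose from 289 to 520 FPKM. Of 13 snoRNA host genes with terminal oligopyrimidine tracts, 12 fell and 1 rose (camera adjusted p = 0.16), among them Gas5, from 4.87 to 2.49 FPKM, and Zfas1, from 7.63 to 3.56 FPKM.

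Among 76 nuclear-encoded genes of oxidative phosphorylation, 34 rose and 22 fell (median 0.34 relative to all genes, camera adjusted p = 2.8e-05, but adjusted p = 0.43 with an estimated correlation). With column totals made equal, which lowers all genes, the list's own median went from 0.11 to −0.01 but stayed at 0.32 relative to all genes. The call was lost with quantile normalization (camera adjusted p = 0.67) and after the length and GC adjustment (0.68). The 4 members with the smallest p went against the list: the ATP synthase gene Atp5b fell from 348 to 172 FPKM, Atp5a1 from 125 to 68.7 FPKM, the complex I gene Ndufv1 from 35.8 to 15.2 FPKM and the complex III gene Uqcrc1 from 57.3 to 25 FPKM. Of 13 mRNAs encoded in the mitochondrial genome, 10 rose and 1 fell (median 0.59 relative to all genes, camera adjusted p = 1.1e-05, but adjusted p = 0.12 with an estimated correlation), with mt-Nd5 going from 111 to 162 FPKM and mt-Co1 from 537 to 757 FPKM. With quantile normalization the median of this list was 0.29 (camera adjusted p = 0.014). Whether these mitochondrial mRNAs were on the polysomes of the fractions was not tested. Of 77 mitochondrial ribosomal proteins, 21 rose and 38 fell (camera adjusted p = 0.19), such as Mrps6, from 175 to 371 FPKM, and Mrpl19, from 23 to 10.9 FPKM. That list's median was −0.12 and its test direction upward, relative to other genes. Counts adjusted over the list alone were the same for these 3 lists.

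Of 30 p53 targets, 16 rose and 9 fell (median 0.50 relative to all genes, camera adjusted p = 2e-05, but adjusted p = 0.10 with an estimated correlation). Cdkn1a (chromosome 17, 29090976 to 29100727), the cell cycle inhibitor p21, rose from 119 ± 4.0 to 250 ± 3.1 FPKM (SD, n = 3), a log2 fold change of 1.06 ± 0.04 (SE, limma adjusted p = 7.77e-09). Mdm2 (chromosome 10, 117688875 to 117710758), the ubiquitin ligase that degrades p53, rose from 22.4 ± 0.81 to 40.7 ± 1.3 FPKM, a log2 fold change of 0.83. The RNA-binding protein gene Zmat3 rose from 11.9 to 25.5 FPKM and the nuclease gene Aen from 13.8 to 27.3 FPKM. Among 27 apoptosis regulators, 6 rose and 17 fell (camera adjusted p = 0.83). Bcl2l1, which encodes the survival protein BCL-XL, rose from 24.0 to 75.9 FPKM, and the pro-apoptotic gene Bmf fell from 5.25 to 1.79 FPKM. Both lists had the same counts adjusted over the list alone.

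Of 40 M2 markers, 22 were tested, the others being absent or under the filter. Among the 22, 8 rose and 10 fell (camera adjusted p = 0.12, upward), and the list's median (−0.11) and mean (0.06) differed in sign. Relative to all genes the median was 0.12, and between 0.07 and 0.14 under the 4 other scalings. Il1rn and Ccl7 rose, the latter a chemokine gene going from 2.12 to 9.28 FPKM, and Klf4, a transcription factor induced by IL-4, fell from 28.9 to 6.15 FPKM. Arg1 (chromosome 10, 24915221 to 24927484) had a log2 fold change of −1.64 ± 0.06 (SE, limma adjusted p = 4.62e-09). Mrc1 (chromosome 2, 14229392 to 14332057) was called lower at −0.20 ± 0.08 (SE, limma adjusted p = 0.033). That call was lost with median-ratio scaling (−0.06), with upper-quartile scaling (−0.08), with the replicate block (adjusted p = 0.051), and without DMSO replicate 2, DMSO replicate 3, BMH-21 replicate 2 or BMH-21 replicate 3, and its sign turned with quantile normalization (0.05). It was also lost with no filter and after the length and GC adjustment. Of 33 M1 markers, 16 were tested, and of these 4 rose and 11 fell (camera adjusted p = 0.87). The costimulatory receptor Cd40 went from 5.45 to 0.775 FPKM and Tlr2 from 24.9 to 11.6 FPKM. Of 13 checkpoint ligands and suppressive mediators, 2 rose and 9 fell (camera adjusted p = 0.65). Cd47, the signal against phagocytosis, fell from 31.5 to 21 FPKM, and the inhibitory receptor gene Lilrb4a rose from 17.2 to 34.1 FPKM. In all 3 lists the counts adjusted over the list alone were the same.

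Of 31 genes of macrophage identity and phagocytosis, 19 rose and 10 fell (median 0.57 relative to all genes, camera adjusted p = 2e-05, but adjusted p = 0.10 with an estimated correlation, and 0.090 with quantile normalization, where the median was 0.21). Lyz1, a lysozyme gene whose reads may be shared with Lyz2, rose from 2869 to 9438 FPKM and the integrin gene Itgb2 from 26.0 to 51.7 FPKM. The fractalkine receptor Cx3cr1 fell from 9.83 to 2.45 FPKM and the antibody receptor Fcgr1 from 36.4 to 17 FPKM. Of 12 osteoclast-lineage genes, 9 rose and 1 fell (median 0.64 relative to all genes, camera adjusted p = 1.2e-05, but adjusted p = 0.12 with an estimated correlation). Examples were the proton pump subunit Atp6v0d2, from 32.4 to 134 FPKM, Dcstamp, a fusion gene of osteoclasts, from 0.626 to 4.29 FPKM, and carbonic anhydrase Car2, from 61.7 to 130 FPKM. Of the 9, Mmp9, chosen after its values were seen, lay at 0.153, 0.170 and 2.57 FPKM in the DMSO libraries and at 3.49, 2.99 and 1.98 FPKM in the BMH-21 libraries. Of 18 immediate early genes, 13 rose and 3 fell (median 0.66 relative to all genes, camera adjusted p = 4e-06, but adjusted p = 0.10 with an estimated correlation), with the AP-1 genes Fos going from 4.49 to 15.4 FPKM and Fosl1 from 0.554 to 3.07 FPKM, and Klf2 falling from 8.28 to 2.59 FPKM. No count of these 3 lists differed when adjusted over the list alone.

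Among 29 NF-kB targets, 8 rose and 15 fell (camera adjusted p = 0.14, upward), and the list's median (−0.19) and mean (0.22) differed in sign. The chemokines Ccl3, from 230 to 768 FPKM, and Ccl4, from 84.9 to 265 FPKM, were among the risers. Of 39 interferon-stimulated genes, 5 rose and 20 fell (camera adjusted p = 0.93), with Ifit2 going from 3.71 to 1.37 FPKM and the ubiquitin-like Isg15 from 82.5 to 56.7 FPKM. Of 19 genes of MHC class I presentation, 2 rose and 15 fell (camera adjusted p = 0.12). The peptide transporter Tap1 fell from 4.95 to 2.07 FPKM and the immunoproteasome subunit Psmb9 from 20.9 to 10.9 FPKM. Of 4 MHC class II genes, too few for a list test, the protease gene Ctss rose and Cd74, Ifi30 and H2-DMa fell. For these 4 lists the counts adjusted over the list alone were the same.

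Of 25 genes of cholesterol synthesis and SREBP2 targets, 16 rose and 7 fell (median 0.47 relative to all genes, camera adjusted p = 2e-05, but adjusted p = 0.10 with an estimated correlation). Insig1, the sterol sensor, rose from 25.3 to 65.6 FPKM and Hsd17b7, an enzyme of sterol synthesis, from 2.77 to 6.25 FPKM. Of 17 genes of LXR and lipid handling, 9 rose and 6 fell (median 0.55 relative to all genes, camera adjusted p = 8.8e-04, but adjusted p = 0.32 with an estimated correlation), such as the fatty acid carriers Fabp5, from 78.4 to 219 FPKM, and Fabp4, from 1.40 to 4.52 FPKM. Among 44 lysosome and autophagy genes, 16 rose and 20 fell (camera adjusted p = 0.077, upward against a median of −0.04). The protease gene Ctsd rose from 1270 to 3684 FPKM and Gpnmb from 354 to 855 FPKM, while the autophagy gene Uvrag fell from 21.7 to 12.3 FPKM. Of 24 NRF2 targets, 6 rose and 15 fell (camera adjusted p = 0.93), with transketolase, Tkt, going from 31.9 to 14.6 FPKM. Within these 4 lists, the counts adjusted over the list alone were the same.

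**Figure D2:**
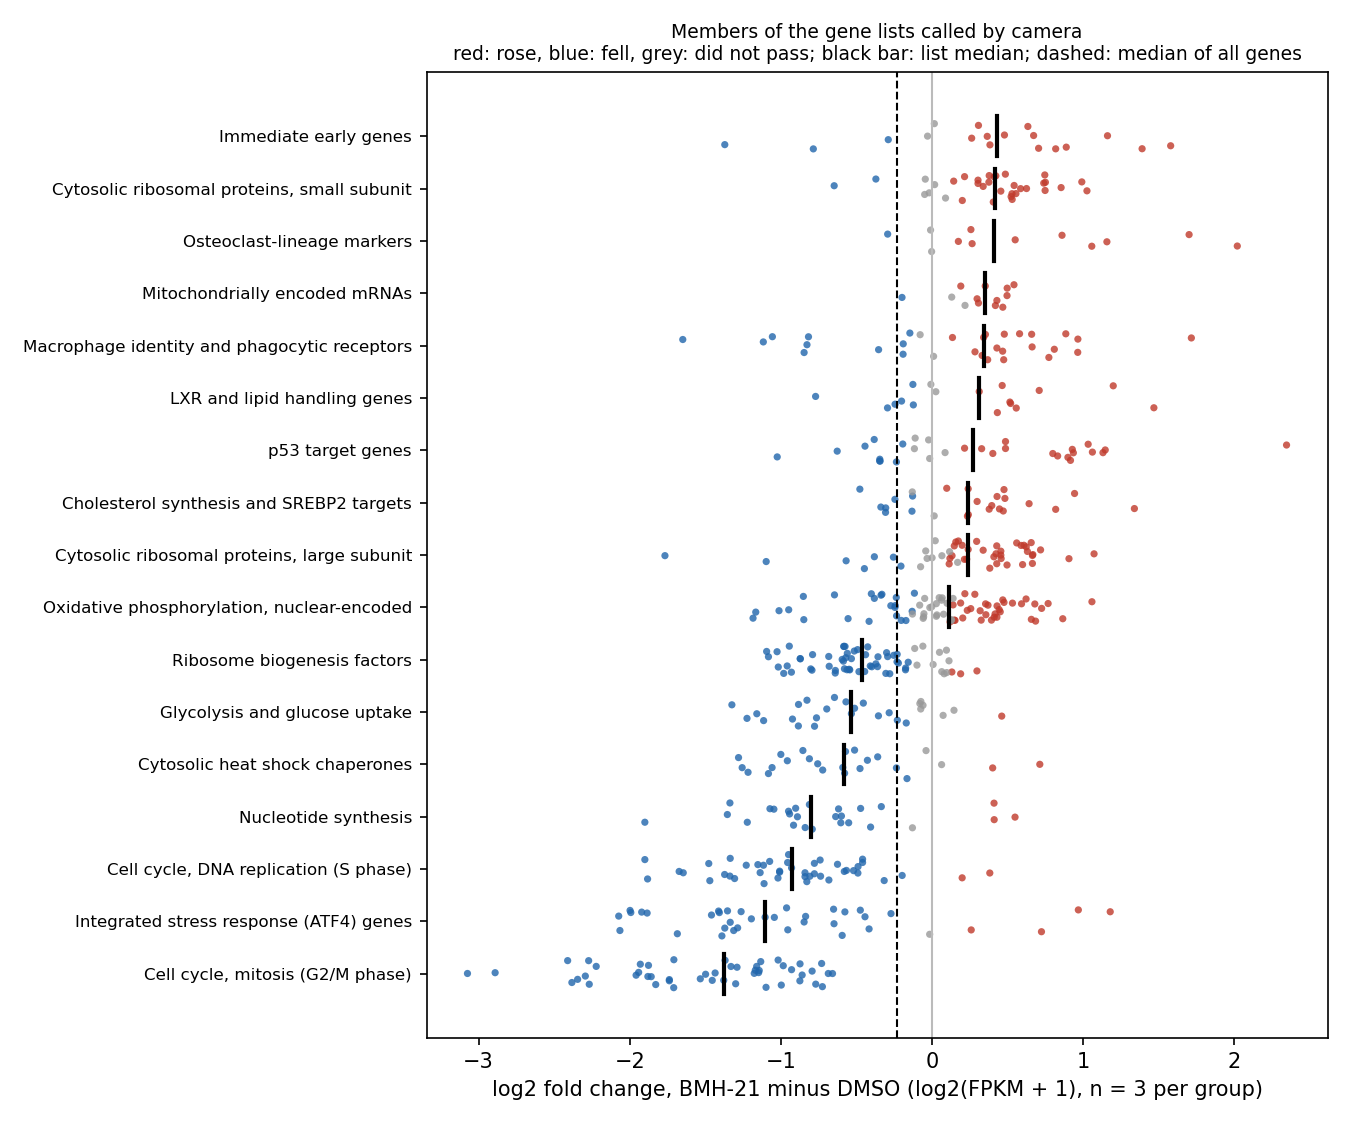
Log2 fold change (BMH-21 minus DMSO, n = 3 per group) of each tested member of the 17 lists called by camera, with red for genes that rose, blue for genes that fell and grey for genes that did not pass, a black bar at the list median and a dashed line at the all-gene median of −0.23. The mitosis list lies lowest, at −1.38, and the median of oxidative phosphorylation, at 0.11, goes to −0.01 when column totals are made equal, where it stays at 0.32 relative to all genes.

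Markers of other cell types were sparse. Of 12 dendritic cell markers, 9 had a row in the table and none of these reached the filter. Of the lymphocyte markers Ighm was tested and fell from 21.9 to 8.59 FPKM. Of the fibroblast, epithelial and endothelial markers, the keratin genes Krt8 and Krt18 were tested and both were called higher. Krt18 was at 0, 0.0644 and 5.47 FPKM in the DMSO libraries and at 8.89, 6.41 and 8.09 FPKM in the BMH-21 libraries. Krt8 was at 0, 0.0236 and 3.27 FPKM in the DMSO libraries and at 4.22, 3.60 and 3.78 FPKM in the BMH-21 libraries. DMSO replicate 3 lay more than 1 log2 unit above both other DMSO libraries in 10 genes, and no other library did so in more than 3. The 10, chosen after their values were seen, were Cpe, Cxcl1, Fn1, Htra1, Krt8, Krt18, Mmp9, Msln, Sparc and Wfdc2, and 6 of them are among the 147 genes called higher by at least 2-fold. Without DMSO replicate 3, 7363 genes were called, 1833 higher and 5530 lower.

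Among the other RNA classes, the ribosomal RNAs of the mitochondrion were chosen after their values were seen. For mt-Rnr2 (log2 fold change 1.11, limma adjusted p = 5.91e-05) the DMSO libraries were at 16.4, 15.8 and 22.9 FPKM and the BMH-21 libraries at 44.8, 45.2 and 32.4 FPKM. For mt-Rnr1 (log2 fold change 0.81, limma adjusted p = 0.034) the groups overlapped, at 10.6, 9.40 and 21.8 against 29.0, 30.0 and 14.8 FPKM. Of 6 nuclear-retained and other non-coding RNAs, 5 fell and 1 rose (camera adjusted p = 0.67). Malat1 went from 9.95 to 4.06 FPKM and Neat1, the scaffold of paraspeckles, from 6.43 to 1.93 FPKM. How nuclear-retained and mitochondrial RNAs came to be in the fractions was not tested. Of the histone list, 4 of 39 symbols had a row in the table and 3 were tested, of which H2ax and H1f0 fell and H1f2 rose; histone genes under other symbols, such as H2ac18, were not in the list. These counts were also the same adjusted over the list alone.

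Change also varied with coding length. Across 9200 genes, which are not independent replicates, the log2 fold change correlated with log2 coding length at Pearson r = −0.25 and Spearman rho = −0.29. Coding sequences of 75 to 498 nt had a median change of 0.17, and those of 1803 to 2244 nt −0.36. The trend turned back for the longest, with −0.29 at 3090 to 22065 nt. Each library's deviation from the gene's mean over all 6 libraries was also fitted on log2 coding length. The slope was 0.0553 to 0.0702 in the DMSO libraries and −0.0767 to −0.0439 in the BMH-21 libraries. The groups did not overlap (3 against 3, for which the smallest exact p is 0.10). These slopes compare the libraries with each other, so their signs do not show how level itself runs with coding length.

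**Figure D3:**
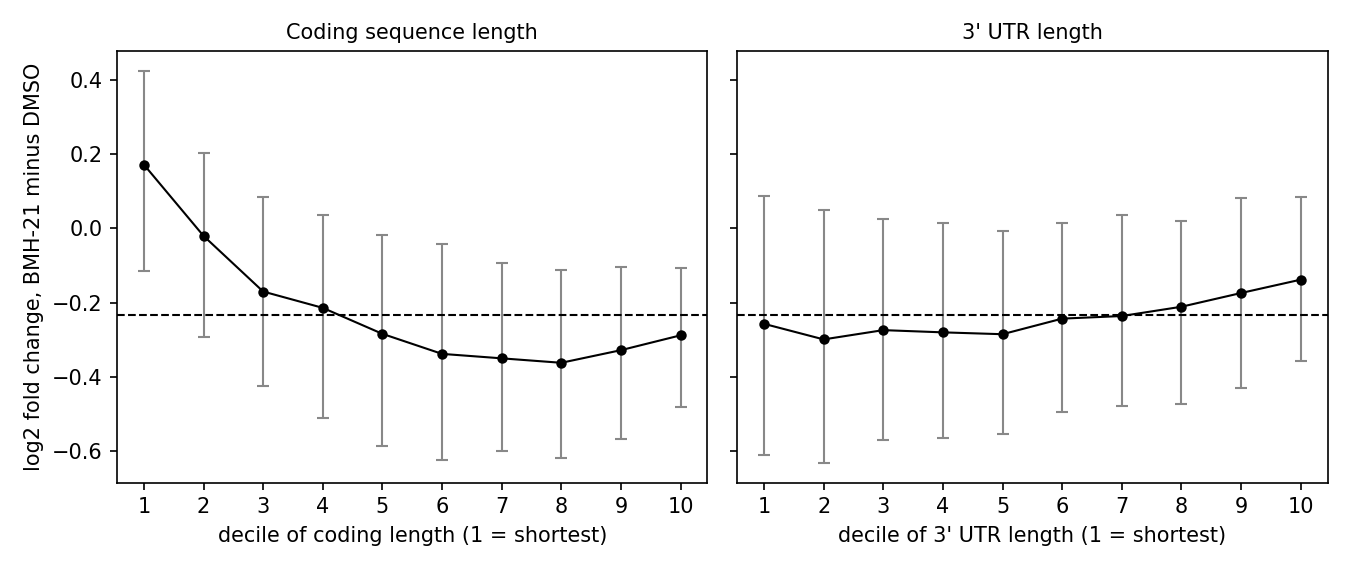
Median log2 fold change (BMH-21 minus DMSO) with quartiles by decile of coding length and of the length of the untranslated region after the stop codon, with the all-gene median dashed. The shortest decile of coding length lies at 0.17 and the eighth at −0.36, while deciles of the untranslated region lie between −0.30 and −0.14.

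In all, camera called 10 lists higher and 7 lower of 33 tested, and each single-library omission gave the same numbers. With no filter, where the all-gene median was −0.04, the relative medians of 12 called lists moved by over 1.5 times, that of LXR and lipid handling to 0.06 (camera adjusted p = 0.011), and all 12 were still called. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.10), with 13 at an unadjusted p under 0.05. The estimate was −0.01 for DNA replication and p53 targets and 0 for nucleotide synthesis, not above the preset 0.01. Yet the unadjusted camera p of DNA replication went from 2.6e-07 to 0.0036. For these lists a larger correlation between members is thus not what ended the call. By contrast fry, which does not compare a list with other genes, called 11 higher and 20 lower.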

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

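Tests with quantile normalization, the robust variance model and the adjustment for coding length, untranslated region length and GC content were chosen after the results were seen. Counts of changed genes stayed between 6893 and 8510 over all alternatives, against 7628. The direction split moved with scaling: 3643 higher and 3546 lower with median-ratio scaling, 3349 higher with upper-quartile scaling, and 3517 higher and 3498 lower with quantile normalization, while equal column totals gave 1389 and 6623. In that order these moved the all-gene median by 0.23, 0.20, 0.24 and −0.10. A pseudocount of 0.1 raised the genes changed at least 2-fold from 658 to 1199, since it damps low genes less. Camera with an estimated correlation called 0 lists higher and 0 lower (13 at an unadjusted p under 0.05), and fry, which tests each list by itself, called 20 lower. Leaving out each library gave 7341 to 7515 changed genes, 1833 to 1889 higher, 5472 to 5658 lower, 662 to 670 changed at least 2-fold, and 10 higher and 7 lower lists each time.

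The replicate block gave 7502 changed genes, 7438 of them shared in direction. Deviations from the group means correlated at −0.112, −0.094 and −0.064 between same-numbered DMSO and BMH-21 libraries. Between differently numbered ones they correlated at 0.005 to 0.097. Same-numbered libraries were thus no more alike than others. Beyond Mrc1, no named gene or list changed its call with the block.

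Direction reversed in these cases, and the cause was not tested: Mrc1 with quantile normalization (0.053), Polr1a with equal totals (−0.015), and lists of which none was called either way, as medians relative to all genes. These were RNA polymerase I with equal totals (−0.011) and over the library omissions from −0.085 (without BMH-21 replicate 1) to 0.026 (without BMH-21 replicate 2), mitochondrial ribosomal proteins with the length adjustment (−0.073), M1 markers with equal totals (−0.148) and without BMH-21 replicate 3 (−0.078, omissions from −0.154), interferon-stimulated genes with quantile normalization (−0.005) and the length adjustment (0.054), NRF2 targets with median-ratio scaling (0.011), upper-quartile scaling (0.006) and the length adjustment (0.021), and non-coding RNAs with no filter (−0.06). List directions here are those of the test. Tug1 lost its call under median-ratio (−0.06), upper-quartile (−0.10) and quantile scaling (−0.06). Lists called only under an alternative were translation factors and MHC class I with no filter or quantile normalization, mitochondrial ribosomal proteins with median-ratio or upper-quartile scaling, M2 markers with the length adjustment, lysosome genes with all 3 of these, and snoRNA hosts with median-ratio or upper-quartile scaling or no filter.

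Not run, for want of counts, were size factors inside edgeR, the DESeq2 test and limma-voom. At an estimated depth of 18780000 to 24080000 reads, genes under the filter of 1 FPKM were left untested, and the log2(FPKM + 1) scale understates changes of genes near it, such as Polr1a, Polr1b and Mrc1.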

Other observations

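Of the tests here, those of the untranslated region, of mixing between libraries and of sample splits were chosen after the results were seen. So were those of the mitosis, small-subunit and oxidative phosphorylation lists under the length adjustment. The test of very short transcripts was chosen after the medians by length, and all gene families were picked by name after the values were seen. Other gene families also moved, and some of them share genes with the lists. Families were matched by patterns in gene symbols, so some hold unrelated genes. Examples are Nupr1 in nuclear transport and Cflar among actin-binding genes. The family named for amino acid transporters holds many carriers of other substances, such as Slc30a1, Slc35a1 and Slc39a1. Its call as higher by camera is therefore not a result about amino acid transporters. Of 31 families looked through, 26 were tested, and camera called 8 higher and 7 lower, but 0 with an estimated correlation. The adjustment for length and GC content ended 4 of these calls, those of kinesins (median −0.39 relative to all genes, from −0.45, camera adjusted p = 0.053), nuclear transport (−0.14 from −0.22, 0.065), actin-binding genes (0.24 from 0.46, 0.082) and RNA polymerase II subunits (0.14 from 0.27, 0.58). All 17 aminoacyl-tRNA synthetase genes fell (median −0.61 relative to all genes, camera adjusted p = 5.5e-05, but adjusted p = 0.13 with an estimated correlation), for example Sars from 93.8 to 34.8 FPKM and Vars from 23.5 to 7.33 FPKM. Aars, Cars, Gars, Mars1, Nars, Sars and Wars are also members of the ATF4 list. Of 39 genes with a proteasome subunit prefix, 35 fell and 1 rose, with Psmc3ip, which is not a proteasome gene, counted among the fallers (camera adjusted p = 6.9e-04, but adjusted p = 0.28 with an estimated correlation), with the ATPase subunit Psmc1 going from 132.8 to 57.9 FPKM. Of 39 genes with splicing factor or hnRNP prefixes, 36 fell and 2 rose (camera adjusted p = 4.7e-04, but adjusted p = 0.13 with an estimated correlation), with Hnrnpa1 going from 137 to 50.0 FPKM. Of 16 genes of the citric acid cycle and its isozymes, 14 fell and 1, cytosolic Idh1, rose from 26.0 to 36.2 FPKM (camera adjusted p = 0.0073, but adjusted p = 0.30 with an estimated correlation). Its mitochondrial counterpart Idh2 fell from 95.1 to 26.7 FPKM.

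Of 17 genes named for the vacuolar proton pump, 13 rose and 2 fell, the pseudogene Atp6v0c-ps2 counted among the risers (camera adjusted p = 1.7e-06, but adjusted p = 0.12 with an estimated correlation). Examples were Atp6v0c, from 376 to 679 FPKM, whose reads a pseudogene shares, and Atp6v1f, from 300 to 531 FPKM. Of 11 chemokine genes, 8 rose and Cxcl2 fell from 6.25 to 3.36 FPKM (camera adjusted p = 4.9e-07, but adjusted p = 0.13 with an estimated correlation). Ccl6 rose from 5.63 to 19.2 FPKM. Cxcl1 did not pass, at 0, 0 and 6.91 FPKM in the DMSO libraries and 7.90, 8.58 and 0.923 FPKM in the BMH-21 libraries. The median directions of these 6 families held under the 4 scalings tried. Chromatin proteins of the HMG group split, with Hmga2 rising from 21.3 to 73.7 FPKM and Hmgb1 falling from 62.3 to 20.9 FPKM. Podoplanin, Pdpn, chosen after its values were seen, rose from 0.455 to 23.4 FPKM.

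A set of 10 genes near 0 in DMSO replicates 1 and 2 was present in DMSO replicate 3 and in the BMH-21 libraries, so their values do not part the groups plainly. RNA of epithelial cells in these 4 libraries is a candidate source, with the epithelial keratin genes Krt18 and Krt8 at 5.47 and 3.27 FPKM in DMSO replicate 3. In a list of 25 epithelial markers that left out the genes already seen, 80% were highest in replicate 3 among the DMSO libraries, where chance gives 33.3% if markers were independent, with Epcam at 0, 0 and 0.483 FPKM, Cdh1 at 0, 0 and 0.425 FPKM, Cldn4 at 0, 0 and 0.998 FPKM and Perp at 0, 0 and 0.725 FPKM, while St14, at 4.54, 4.48 and 4.24 FPKM, and Sfn were also found in the other DMSO libraries. BMH-21 libraries mixed into DMSO replicate 3 were argued against, since the other 141 genes that rose at least 2-fold lay in replicate 3 at a median of 0 of the way from the other DMSO libraries to BMH-21, against 0.863 for the 10. Whether such RNA came with the cells or in library preparation, and whether it accounts for genes such as Mmp9, Fn1 and Sparc that other cells also make, stays open, and no biological explanation was tested.

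The fold change fell by 0.12 per doubling of coding length (SE 0.0049), although it turned back in the longest deciles. A length effect of the libraries or of the FPKM scaling as the whole cause was argued against by the untranslated region, whose coefficient was 0.031 (SE 0.003) in the opposite sense to coding length (−0.0945). Ribosomal and mitochondrial protein genes alone did not account for it, as the slope was −0.113 without them, nor did very short transcripts, as it was −0.097 among those of 2000 nt or longer. An effect of BMH-21 on how short and long mRNAs are loaded with ribosomes, a change in their abundance, and a difference in fraction handling between the groups stay open, as none of these was tested.

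Whether that trend lies behind the list changes was tested after adjusting each library for coding length, untranslated region length and GC content, with medians relative to all genes. The mitosis list stayed at −1.112 (from −1.146), the tRNA synthetases at −0.668 (from −0.614), and the small-subunit ribosomal proteins at 0.437 (from 0.65), which argues against the trend as their whole cause. The oxidative phosphorylation list dropped to 0.078 (quartiles −0.066 to 0.261) from 0.342 (0.053 to 0.609), and its call ended because the median shrank (adjusted p = 0.68), so its rise may come from the trend. The drug, a batch that follows the groups, and fraction handling stay open for all of these. The 10 genes with the most estimated reads, among them Lyz2 and Spp1, took 6.19% to 6.24% of estimated reads in DMSO and 11.25% to 11.72% in BMH-21. With these genes left out and the estimated read totals of the rest made equal, the all-gene median was −0.164 in place of −0.23.

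The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7628 changed genes and 658 changed at least 2-fold, and the highest other split gave 0 of each. Only 1 of the 10 splits reached each count. Every other split put both treatments in both groups, so the treatment difference entered the spread within groups. Their count of 0 therefore does not measure how many false calls the test makes. For lists called by camera the real split gave 17 and the highest other split also gave 17. So 2 of the 10 reached that count, and the remaining splits gave 12 to 15. The mixed groups held unequal shares of the treatments, so part of the treatment difference remained between them. Their list counts are therefore not counts without a treatment difference, and no conclusion is drawn from them.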
